A study of Mus musculus with 5 samples.

How the data were processed

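Gene expression was measured in aortas of male mice carrying the db mutation of the leptin receptor gene Lepr. Homozygous db/db mice, which lack the signalling form of the receptor and become obese and diabetic, were set against heterozygous db/+ mice of the same colony. Mice were 16 to 20 weeks old and ate regular chow, per the labels. Per the series' design text, adventitia and periaortic fat were stripped off and each hybridised sample held the RNA of 6 aortas. Biotin-labelled cRNA was made from 10 µg of RNA, per the labels' protocols. The design text describes independent pools in triplicate for each genotype. The arrays analysed here were 3 of db/db (replicates 1, 2 and 3) and 2 of db/+ (replicates 2 and 3); a further db/+ pool was not analysed here. An array is therefore 1 pool, and the spread between arrays is the spread between pools, which is smaller than that between single mice.

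The deposited values were linear signal intensities per probe set that the authors computed with MAS5, per the submitters' processing notes, which give no version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 background-corrected signal and scales each array to a common trimmed mean. In the deposited table the 2% trimmed mean was between 150.05 and 150.053 on every array, so the values were used without further normalization. Detection calls were not used here. Median signals lay between 59 and 61.5, and between 19.0% and 22.0% of the probe sets of an array had a signal under 16. The number of arrays limits the precision of every value.

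The table held 22690 probe sets, of which 64 were controls and were left out. The platform annotation gave 1 gene symbol for 20380 of the remaining 22626 probe sets, several for 691 and none for 1555; probe sets with several or none were tested but not named. An Entrez identifier in the RefSeq gene table of assembly GRCm38.p6 matched 20351 of the named probe sets, and no symbol needed updating. That table served only for names and for which genes neighbour each other, because the genome build behind the array was not given in the sources used here, and no coordinates are printed. Genes not named in this annotation were not analysed here.

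Values were transformed to log2(signal + 16), so a log2 change is on that scale and understates the change of genes with low signals. Probe sets were kept if their mean over the 5 arrays was above the 40th percentile, which corresponds to a signal of about 39.5. The 13575 probe sets kept represented 8263 named genes. Each was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. The fit left 3 residual degrees of freedom, to which the prior added 5.63. The comparison was between genotypes, in direction db/db minus db/+.

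Before the data were examined, 32 gene lists were fixed, covering cell types of the vessel wall, tissues that may stay attached to an aorta and pathways tied to diabetes, oxidant production and inflammation. Of their 1043 members, 916 had a probe set. Lists with at least 5 measured members, 31 of the 32, were tested with limma's camera at a preset correlation of 0.01 against all other genes, with 1 probe set per gene (the one with the highest mean) and Benjamini-Hochberg adjustment over lists. Members past the threshold over all probe sets, and with the p adjusted over the list alone, were counted by that representative probe set. The erythrocyte list had 2 measured members and was not tested. A further 3 lists (hepatocyte, mast cell and mesothelial markers) were written after the most changed genes had been seen, and stand outside that adjustment.

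The genes named were chosen by a rule set before the data were examined. It took Lepr and 1 further item that is not reported here, then 15 genes higher and 15 lower in db/db whose arrays did not overlap between genotypes, first those past the threshold by size and then those with the smallest unadjusted p, and then up to 4 members of each list with the smallest unadjusted p. Genes outside the rule are named as such. Where probe sets of a gene disagreed, the text says so.

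Alternatives set beforehand were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, a threshold of 0.1, camera with an estimated correlation, fry, and the mean of a gene's probe sets. The test was tried on simulated data with the real means and spreads drawn from limma's fitted prior, 13575 probe sets in each of 10 runs, of which 200 were changed. It found 98.5% of 4-fold and 53% of 2-fold changes, 5.13% of its calls were false, and 0 had the wrong sign. In 20 simulated runs over 8263 genes, camera with the preset correlation called 100% of 24-gene lists shifted by −0.5 and 0% of unshifted lists, and with an estimated correlation it called 15% of the shifted lists. Simulated genes were independent, so these shares do not cover lists whose members vary together. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.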

Results

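Affymetrix expression arrays of mouse aorta were analysed, 3 from leptin receptor mutant db/db mice and 2 from heterozygous db/+ mice, each a separate pool of 6 aortas. MAS5 signals were given for 22690 probe sets, and 13575 of them lay above the filter on low signals. Log2 signals of any pair of arrays correlated across probe sets with r between 0.952 and 0.977, and db/db replicate 1 stood somewhat apart, with r between 0.952 and 0.965. Ratios of the 3' to the 5' actin probe sets, a measure of RNA integrity, lay between 1.14 and 1.34. Values below are mean signal ± SD, n = 3 for db/db and n = 2 for db/+, and log2 changes are db/db minus db/+ with the standard error (SE) from limma.

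Lepr was measured first, as the gene whose mutation separates the groups. Its signal was 81.2 ± 9.67 in db/db and 65.4 ± 8.70 in db/+, a log2 change of 0.26 (SE 0.17, limma adjusted p = 0.77). The db mutation alters splicing of the receptor's signalling form, and which forms this probe set reads was not examined here, so the signal does not check the genotype labels. Of 13 measured neighbours of Lepr on chromosome 4, 0 passed the test, over all probe sets or with the p adjusted over the list alone, and the list's mean log2 change was 0.18 (camera adjusted p = 0.074). The list passed without db/+ replicate 2 (adjusted p = 0.012) and without db/db replicate 2 (adjusted p = 0.045). Its members with the smallest p were Ak4, Nfia, Pgm1 and Dab1, with log2 changes of 0.69, 0.46, 0.26 and 0.32.

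The series compared aortas of diabetic db/db mice with those of db/+ mice. The changes that passed were all decreases in db/db. The fat hormone leptin, Lep, fell from 283 ± 26.7 to 23.5 ± 11.5, a log2 change of −2.96 (SE 0.24, adjusted p = 0.0073), and its db/db signal lay under the filter's level of 39.5, where folds are understated. Nnat, which encodes neuronatin, had a log2 change of −3.11 (SE 0.33, adjusted p = 0.020), from 1032 ± 617 to 94.8 ± 14.3. Sncg, the synuclein gene of neurons and adipocytes, had 410 ± 27.7 in db/+ and 104 ± 2.12 in db/db, a log2 change of −1.82 (SE 0.15, adjusted p = 0.0073). The liver-type transcripts Alb (albumin) and Bhmt (a methyltransferase of homocysteine) had log2 changes of −2.24 (SE 0.20) and −1.93 (SE 0.22), with adjusted p = 0.0090 and 0.024. Log2 changes from −1.50 to −1.38 were found for Npr3, the clearance receptor of natriuretic peptides, the stress-responsive kinase gene Plk2, the lubricin gene Prg4, and Cyp1b1, a cytochrome P450 of vessel cells, whose second probe set had a log2 change of −1.10 (adjusted p = 0.084).

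With limma at an adjusted p under 0.05, 11 probe sets were lower and 0 higher in db/db, and at an unadjusted p under 0.05 there were 564 lower and 540 higher. Those 1104 exceed the 678.75 expected by chance, but other splits of the 5 arrays into 3 and 2 gave from 303 to 1115, the highest with db/db replicates 1 and 3 set apart. The 11 probe sets stood for 9 genes by their representative probe set, plus a second probe set of Serpina1b (−2.17, SE 0.21, adjusted p = 0.014) and of Lyve1 (−1.36, SE 0.18, adjusted p = 0.047), 2 genes named after their values were seen. The representative probe sets of Serpina1b and Lyve1 had log2 changes of −1.29 (adjusted p = 0.061) and −0.87 (adjusted p = 0.44), and both probe sets of Serpina1b are of a type that can also read related genes. Arrays of the 2 genotypes did not overlap at 3394 probe sets (25% of those tested, where chance gives 20% and the same other split gave 3484 probe sets). The number of calls was 0 without db/+ replicate 2 (with 761 probe sets at an unadjusted p under 0.05) and 1 without db/+ replicate 3, fits that leave 1 db/+ array. Without db/+ replicate 2 the log2 changes of Lep, Alb, Sncg and Prg4 were −2.87, −2.39, −1.76 and −1.39, with adjusted p from 0.10 to 0.36. It was 28 without db/db replicate 1, 2 with a pseudocount of 1 (Alb and Sncg), 1 with no filter on low signals and 48 with array weights.

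**Figure D1:**
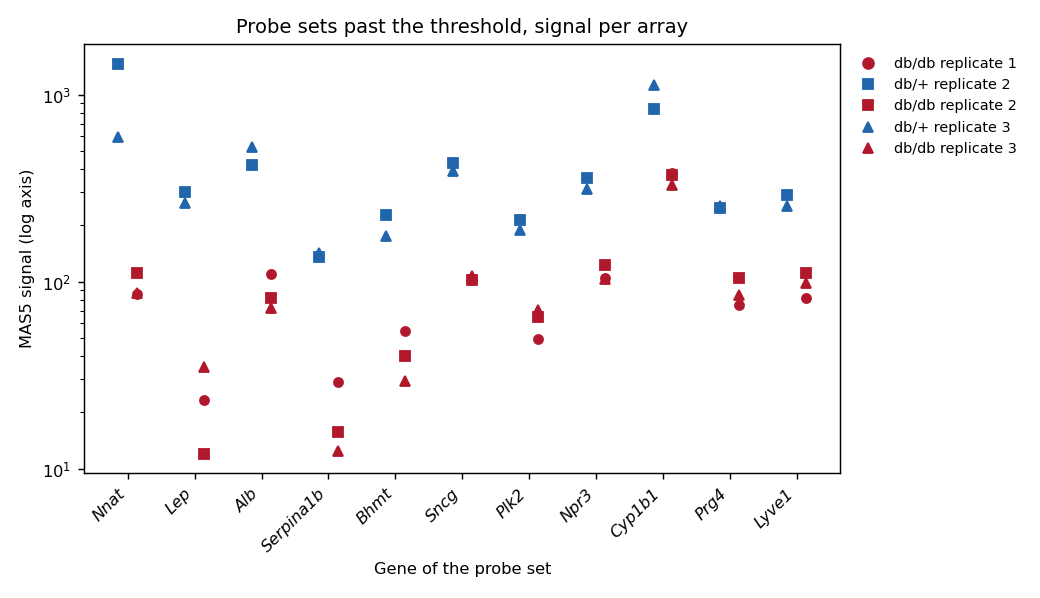
MAS5 signal (log axis) of each of the 11 probe sets past the threshold, labelled by gene, with 1 point per array, blue for db/+ (2 arrays) and red for db/db (3 arrays). In every one of these probe sets the db/db points lie below the db/+ points.

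A further 6 genes completed the 15 lower ones, with adjusted p between 0.052 and 0.056, so that they did not pass. They were the secreted protease inhibitor Slpi (−1.31, SE 0.18), the chemokine Ccl6 (−1.19, SE 0.16), the sulfotransferase Chst15 (−1.24, SE 0.17), the lipase inhibitor Angptl4 (−1.36, SE 0.19), the macrophage lectin Lgals3 (−1.15, SE 0.16) and the lysozyme gene Lyz1 (−1.33, SE 0.19). The probe set of Lyz1 can also read its close copy Lyz2, and another probe set of Lyz1 had a log2 change of 0.05. In a list of 23 measured liver cell markers, written after Alb, Bhmt and 3 further members had been seen, 18 had a negative log2 change, and adjusted over the list alone 14 were lower and 3 higher (Cyp2e1, Apoa1 and Itih3, at 0.86, 0.81 and 0.50). The mean was −0.62 over all members and −0.36 over the 18 not first seen (camera p = 1.1e-05 unadjusted for these 18; p = 0.077 with an estimated correlation).

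None of the 15 higher genes passed the threshold. Efnb2, the arterial ephrin ligand, had 313 ± 93.5 in db/db and 88 ± 4.67 in db/+ (log2 change 1.62, SE 0.24, adjusted p = 0.060), but a second probe set of Efnb2 went the other way (−0.83, SE 0.17). That second probe set became the brighter one without db/db replicate 1 or 3, which turned the value of Efnb2 to −0.78 and −0.92. Lmcd1, a LIM-domain cofactor of muscle, had 3093 ± 281 against 1493 ± 41.7 (1.04, SE 0.16, adjusted p = 0.061). Cxcl14, Pcp4l1 and Lratd1 had log2 changes of 1.16, 0.98 and 1.35, with adjusted p from 0.064 to 0.084. The other genes were Adamts8, Nrgn, Yars, Acot11, H2-Eb1, Fasn, Echdc1, AU020206, Dcx and Gapdhs, with log2 changes from 0.68 for AU020206 to 1.42 for Acot11 and adjusted p from 0.13 to 0.20.

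Of the 31 gene lists tested, camera with its preset correlation placed 12 past the threshold, 3 higher and 9 lower in db/db. With an estimated correlation 0 of the 31 passed, with 3 at an unadjusted p under 0.05, and with fry 0 passed, with 5. At 4 of the 10 ways to split the 5 arrays into 3 and 2, the true one included, at least 12 lists passed, and the highest number was 16. With a filter at the 60th percentile the white adipocyte, antioxidant, extracellular matrix and proliferation lists no longer passed (camera adjusted p = 0.12, 0.053, 0.062 and 0.10). At that filter 29 lists were tested and 8 passed, 7 of the 12 among them. The lymphocyte list was not tested there, because fewer than 5 of its members were kept.

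**Figure D2:**
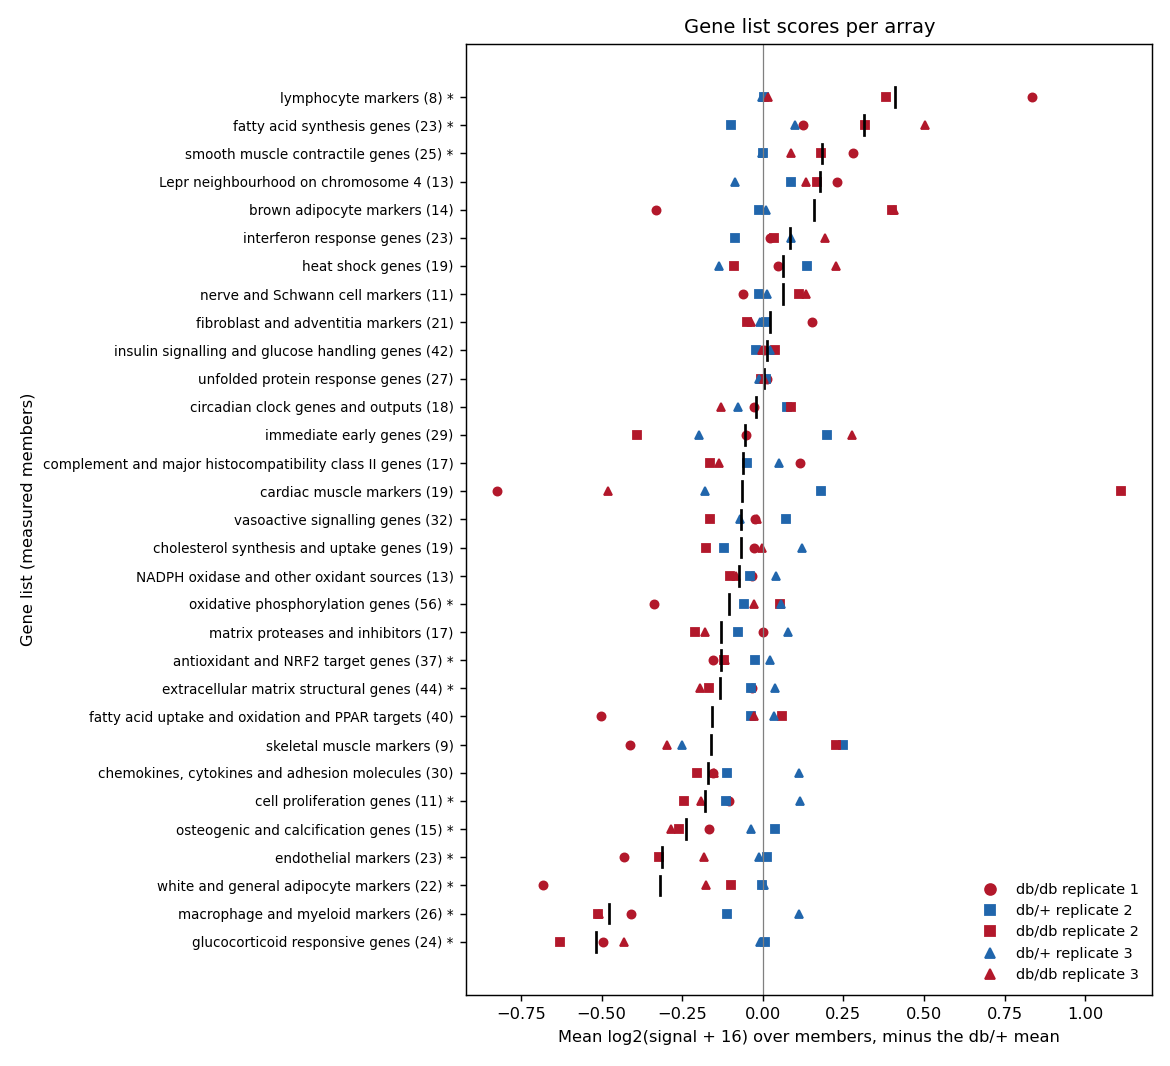
Mean log2(signal + 16) over the measured members of each of the 31 gene lists tested, minus the mean of the 2 db/+ arrays, with 1 point per array (blue for db/+, red for db/db), a black bar at the db/db mean, members in brackets and an asterisk at lists past the threshold with the preset correlation. Of these 31 the glucocorticoid and myeloid lists lie lowest, and db/db replicate 1 lies apart from the other db/db arrays in the white fat, brown fat and oxidative phosphorylation lists.

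Glucocorticoid responsive genes had the lowest mean among the 31 lists (mean log2 change −0.52 over 24 members, camera adjusted p = 2.5e-11; adjusted p = 0.13 with an estimated correlation). No member passed over all probe sets, while 11 of the 24 were lower with the p adjusted over the list alone and 22 had a negative log2 change. The members with the smallest p were Angptl4, the metallothionein Mt2 (987 ± 181 against 1812 ± 10.6, log2 change −0.88), the kinase gene Map3k6 (−0.70) and the tyrosine aminotransferase gene Tat (−0.74), which the added hepatocyte list also holds.

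Macrophage and myeloid markers shifted down as well (mean log2 change −0.48 over 26 members, camera adjusted p = 2.5e-11; adjusted p = 0.35 with an estimated correlation). Over all probe sets 0 members passed, and adjusted over the list alone 13 were lower and 1 was higher. Besides Lgals3 and Lyz1, the Fc receptor gamma chain Fcer1g had 41.7 ± 20.6 in db/db and 156 ± 22.8 in db/+ (−1.63, SE 0.27, adjusted p = 0.078) and Lyz2 had 562 ± 103 and 1206 ± 127 (−1.09, SE 0.19, adjusted p = 0.10). The 8 measured lymphocyte markers shifted up (mean 0.41, camera adjusted p = 0.011; adjusted p = 0.65 with an estimated correlation), with 0 passing over all probe sets or adjusted over the list alone. Zap70, Cd79b, Cd37 and Jchain had log2 changes of 0.78, 0.49, 0.36 and 0.55, and the list's mean was 0.13 (adjusted p = 0.26) without db/db replicate 1.

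Chemokines, cytokines and adhesion molecules did not pass as a list (mean −0.17, camera adjusted p = 0.074). No member of the 30 passed over all probe sets, and adjusted over the list alone 4 were lower and 2 higher. Ccl6 was followed by Ccl9 (−1.13, SE 0.17), Cxcl14 and the adhesion receptor Selp (−0.94, SE 0.16). The list passed with a filter at the 60th percentile (mean −0.29, camera adjusted p = 0.0012), with no filter (0.047), without db/db replicate 1 (0.027) and without db/db replicate 3 (0.042). Without db/+ replicate 2 its mean was −0.28. Over 15 settings with the preset correlation its mean ranged from −0.29 to −0.05. Complement and class II genes did not pass (mean −0.06, camera adjusted p = 0.32), with 0 of 17 over all probe sets and, adjusted over the list alone, 3 higher and 6 lower. The class II gene H2-Eb1 had 449 ± 23.5 in db/db and 266 ± 14.5 in db/+ (0.72, SE 0.15), while C3ar1, C1qc and Cfb had log2 changes of −0.69, −0.71 and −0.64. Without db/db replicate 1 this list passed (mean −0.20, adjusted p = 0.028). Interferon response genes did not pass (mean 0.08, camera adjusted p = 0.33; 0 of 23 by either count), and Iigp1, Ifih1, Bst2 and Gbp2 had log2 changes of 0.76, −0.50, −0.66 and 0.41.

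Among markers of vessel wall cells, smooth muscle contractile genes shifted up (mean 0.18 over 25 members, camera adjusted p = 0.0049, and 0.65 with an estimated correlation). By either count 0 members passed. Ramp1, a receptor partner of calcitonin gene-related peptide, had 1534 ± 32.5 in db/db and 1044 ± 89.9 in db/+ (0.55, SE 0.15), Mustn1 and the potassium channel subunit Kcnmb1 had 0.50 and 0.44, and Notch3 had −0.42. Endothelial markers shifted down (mean −0.31 over 23 members, camera adjusted p = 3.5e-06; adjusted p = 0.35 with an estimated correlation), with 0 passing by either count of representative probe sets, although the second probe set of Lyve1, a lymphatic marker in this list, passed. Pecam1 had 256 ± 47.6 and 467 ± 65.1 (−0.84, SE 0.19), Vwf had −0.57 and Esam −0.48. Fibroblast and adventitia markers did not shift detectably (mean 0.02, camera adjusted p = 0.93; 0 of 21 by either count), and Dpep1, Entpd2, Fndc1 and Ogn had log2 changes of −0.61, 0.56, −0.51 and 0.35.

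Ucp1, the uncoupling protein of brown fat, and Adipoq, the adipocyte hormone adiponectin, were chosen after their values were seen. Ucp1 had 3305 ± 1106 in db/db and 2584 ± 114 in db/+, and Adipoq had 1822 ± 372 and 2456 ± 473. Transcripts of fat were therefore measured in every array, although the design text says that periaortic fat was stripped off. White and general adipocyte markers shifted down (mean −0.32, median −0.13 over 22 members, camera adjusted p = 0.010; adjusted p = 0.81 with an estimated correlation), with 1 member, Lep, lower by both counts. Retn, Cebpa and Pparg had log2 changes of 0.49, −0.46 and −0.94. Without db/db replicate 1 the mean was −0.14 (adjusted p = 0.37). Brown adipocyte markers did not pass (mean 0.16, camera adjusted p = 0.34), with 0 of 14 over all probe sets and 2 higher adjusted over the list alone, the thioesterase gene Acot11 and the elongase gene Elovl3 (1.16, SE 0.27). Fabp3 and Ppargc1b had −1.12 and −0.33, and without db/db replicate 1 the brown list passed (mean 0.40, adjusted p = 0.00016).

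**Figure D3:**
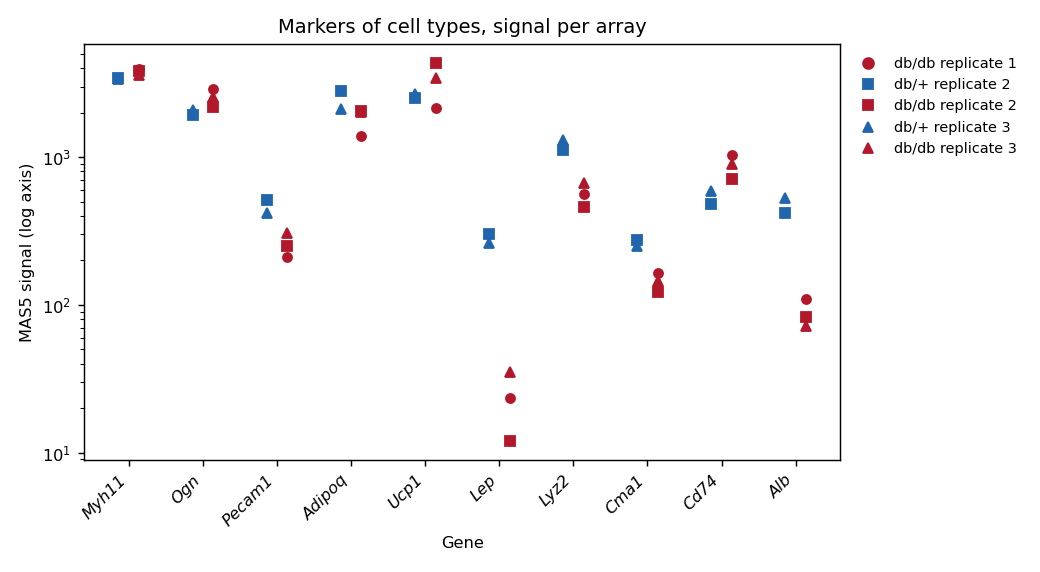
MAS5 signal (log axis) of 10 genes that mark cell types, chosen for display after their values were seen, with 1 point per array, blue for db/+ (2 arrays) and red for db/db (3 arrays). Ucp1 and Adipoq exceed 1000 in every array, and Lep lies between 12 and 36 in the db/db arrays.

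Other tissues that can stay attached to an aorta showed no list shift past the threshold. Cardiac muscle markers had a mean of −0.06 (camera adjusted p = 0.72, 0 of 19 by either count). Single arrays ranged from −0.82 in db/db replicate 1 to 1.11 in db/db replicate 2 relative to db/+. The list therefore passed downward without db/db replicate 2 (mean −0.64, camera adjusted p = 6.7e-07). It passed upward with the replicate number as a block (0.32, 0.020), where db/db replicate 1 adds nothing to the estimate. Without db/db replicate 1 its mean was 0.35 (camera adjusted p = 0.088). Nppb, Myl3, Myl2 and Myl4 had log2 changes of 0.67, −1.19, −0.81 and 0.47. Skeletal muscle markers had a mean of −0.16 (camera adjusted p = 0.81), with 0 of 9 over all probe sets and 1, Casq1 (0.65, SE 0.17), higher adjusted over the list alone, while Tnnc2, Ckm and Acta1 had −0.98, −0.50 and −0.92 (Acta1 0.22 without db/+ replicate 2). Without db/+ replicate 3 the skeletal list passed (adjusted p = 0.049). Nerve and Schwann cell markers had a mean of 0.06 (camera adjusted p = 0.67; 0 of 11 by either count), with Th, Dbh, S100b and Pmp22 at 0.36, 0.30, −0.29 and 0.18. The 2 measured erythrocyte genes, Alas2 and Klf1, had 0.54 and −0.04 (Klf1 0.14 without db/+ replicate 2).

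Genes of fatty acid synthesis shifted up (mean 0.31 over 23 members, camera adjusted p = 0.00014; adjusted p = 0.65 with an estimated correlation). Over all probe sets 0 passed, and adjusted over the list alone 1 was higher, the fatty acid synthase gene Fasn. It had 2972 ± 309 in db/db and 1356 ± 568 in db/+ (1.18, SE 0.25), and its log2 change ranged from 0.75 to 1.62 over 15 settings. Elovl6, Acly and Elovl5 had log2 changes of 0.85, 0.70 and 0.46. Fatty acid uptake and oxidation genes did not pass (mean −0.16, camera adjusted p = 0.065), with 0 of 40 over all probe sets and 1 lower adjusted over the list alone, Angptl4, while Acsl5, Ucp3 and Pdk4 had 0.63, 0.55 and −0.83. That list passed without db/db replicate 2 (camera adjusted p = 0.00052), without db/db replicate 3 (0.0061) and with the mean of each gene's probe sets (0.017). Its mean was −0.19 without db/+ replicate 2. Without db/db replicate 1 its mean turned to 0.016 (camera adjusted p = 0.56).

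Oxidative phosphorylation genes shifted down (mean −0.10 over 56 members, camera adjusted p = 0.013; adjusted p = 0.86 with an estimated correlation), with 0 passing by either count and Atp5k, Ndufs1, Atp5c1 and Cox5a at 0.71, −0.41, −0.29 and −0.36, and other probe sets of Atp5k at −0.05 and 1.15. This shift followed db/db replicate 1, where the mean was −0.34, and without it the list's mean was 0.02 (adjusted p = 0.85). It did not pass without db/+ replicate 3 either (mean −0.05, adjusted p = 0.26). Cholesterol synthesis and uptake genes did not pass (mean −0.07, camera adjusted p = 0.30; 0 of 19 by either count), with Fdft1, Sc5d, Msmo1 and Tm7sf2 at −0.50, −0.33, −0.23 and 0.28 (0.42 at the second probe set of Sc5d), although without db/+ replicate 2 they did (adjusted p = 0.016). Insulin signalling and glucose handling genes had a mean of 0.01 and a median of −0.0028 (camera adjusted p = 0.90, direction up, 0 of 42 by either count). Pygm, Pdk4, Pfkl and Socs2 were at 0.52, −0.83, 0.68 and 0.49.

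Antioxidant and NRF2 target genes shifted down by a small amount (mean −0.13 over 37 members, camera adjusted p = 0.021; adjusted p = 0.35 with an estimated correlation). Over all probe sets 0 passed, and adjusted over the list alone 3 were lower, namely the retinaldehyde dehydrogenase gene Aldh1a1 (145 ± 26.9 against 363 ± 47.8, −1.24, SE 0.19), Mt2 and the plasma glutathione peroxidase gene Gpx3 (−0.88, SE 0.19). Mt1 had −0.57. The list did not pass without db/db replicate 1 (mean −0.11, adjusted p = 0.074) and without db/+ replicate 3 (mean −0.09, adjusted p = 0.10). NADPH oxidase and other oxidant sources did not pass (mean −0.07, camera adjusted p = 0.34), with 0 of 13 over all probe sets and 1 lower adjusted over the list alone, the leukotriene pathway gene Alox5ap (−0.77, SE 0.17). Xdh, Nos1 and Cybb had −0.42, 0.40 and −0.24. Nox4, chosen after its value was seen, had 882 ± 68.3 in db/db and 919 ± 46.8 in db/+ (−0.06, SE 0.16; 0.05 at its second probe set).

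Extracellular matrix genes shifted down (mean −0.13 over 44 members, camera adjusted p = 0.013; adjusted p = 0.81 with an estimated correlation). Over all probe sets 0 passed, and 4 were lower adjusted over the list alone, Thbs1 (71.9 ± 18.9 against 205 ± 57.1, −1.33), Comp (−0.94), Acan (−0.83) and Fbln2 (−0.82). The list did not pass without db/+ replicate 3 (mean −0.09, adjusted p = 0.088) and without db/db replicate 3 (mean −0.10, adjusted p = 0.12). Osteogenic and calcification genes shifted down (mean −0.24 over 15 members, camera adjusted p = 0.014; adjusted p = 0.35 with an estimated correlation), with 0 over all probe sets and 5 lower adjusted over the list alone, among them Comp, Acan, the liver-made calcification inhibitor Ahsg (−0.84) and Bmp4 (−0.63). With no filter on low signals this list did not pass (adjusted p = 0.14). Matrix proteases and inhibitors did not pass (mean −0.13, camera adjusted p = 0.13), with 0 of 17 over all probe sets and 2 lower adjusted over the list alone, Timp4 (197 ± 8.49 against 416 ± 17.7, −1.02) and Mmp3 (−0.74), and Timp1 and Adamts5 had −0.56 and 0.24 (−0.02 at the second probe set of Adamts5). Timp1 had a signal of 240.5 in db/+ replicate 2 and 523 in db/+ replicate 3, and its log2 change ranged from −1.1 to −0.029 over 15 settings. The protease list passed without db/db replicate 1 (mean −0.19, camera adjusted p = 0.027). With the replicate number as a block the list passed too (0.020), at the same mean, because that array adds nothing to the block's estimate. Without db/+ replicate 2 its mean was −0.21. Over 15 settings with the preset correlation its mean ranged from −0.21 to −0.053.

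Vasoactive signalling genes did not shift as a list (mean −0.07, camera adjusted p = 0.34), and Npr3 was the 1 of 32 members that fell, by both counts. Adm, Gucy1a1 and Ramp2 had log2 changes of −0.60, 0.52 and −0.35. Circadian clock genes and outputs did not pass (mean −0.02, camera adjusted p = 0.55), with 0 of 18 over all probe sets and 1 lower adjusted over the list alone, Cry2 (82.0 ± 7.15 against 143 ± 17.3, −0.70), while Nr1d1, Per2 and Bhlhe40 had 0.58, −0.72 and 0.69.

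Proliferation genes shifted down (mean −0.18 over 11 members, camera adjusted p = 0.036; adjusted p = 0.57 with an estimated correlation), with 0 by either count and Ccnd1, Cdc20, Pcna and Mcm3 at −0.54, −0.45, −0.48 and −0.19. The list did not pass without db/db replicate 2 (mean −0.11, adjusted p = 0.26), db/+ replicate 3 (mean −0.09, adjusted p = 0.29) or db/db replicate 3 (mean −0.17, adjusted p = 0.077). Immediate early genes did not pass (mean −0.05, camera adjusted p = 0.34, 0 of 29 by either count). Cebpd, Maff, Fosl2 and Ier5 were at −0.59, −0.64, 0.35 and 0.48 (0.03 at the second probe set of Cebpd). The list passed without db/db replicate 3 (mean −0.23, camera adjusted p = 0.0021), and its mean was −0.25 without db/+ replicate 3. Its mean turned to 0.14 without db/+ replicate 2 and to 0.10 without db/db replicate 2. Heat shock genes did not pass (mean 0.06, camera adjusted p = 0.55; 0 of 19 by either count), with Hspa4, Cryab, Stip1 and Chordc1 at −0.46, −0.43, 0.23 and 0.27, and passed without db/+ replicate 2 (adjusted p = 0.017). Unfolded protein response genes had a mean of 0.0031 and a median of 0.05, against a downward direction in the test (camera adjusted p = 0.98; 0 of 27 by either count), with Ddit3, Sdf2l1, Dnajc3 and Atf4 at 0.46, 0.29, −0.46 and −0.32, and other probe sets of Dnajc3 from −0.32 to 0.00032.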

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

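The alternatives were set before the data were examined. The 11 probe sets past the threshold became 2 with a pseudocount of 1, 37 with a pseudocount of 64, 1 with no filter (0 of it shared with the 11), 22 with a filter at the 60th percentile, 19 with median centring, 39 with eBayes with trend and robust, 48 with array weights and 48 at an adjusted p under 0.1. Calls remained mostly lower, 34 of 37 with a pseudocount of 64 and 41 of 48 with array weights, and all 11 were kept in both. Leaving out 1 array gave between 0 (without db/+ replicate 2) and 28 (without db/db replicate 1), and in the fits with 1 db/+ array left, that array was assumed to vary like the others. With the replicate number as a block, 20 probe sets passed (8 of the 11 among them) and 10 lists (7 of the 12), without the smooth muscle contractile (mean 0.13, camera adjusted p = 0.053), white adipocyte (−0.14, 0.37), lymphocyte (0.20, 0.067), antioxidant (−0.12, 0.058) and oxidative phosphorylation lists (0.013, 0.96). Only 2 numbers occur in both genotypes. No db/+ array shares the number of db/db replicate 1, so under the block that array adds nothing to the genotype estimate. The block is therefore not a check apart from leaving that array out, and the white adipocyte mean was −0.14 in both. Same-numbered arrays deviated from their group means with correlations of 0.11 and −0.0048. With 2 db/+ arrays these values are not independent and cannot decide whether the numbers mark a shared batch. The labels do not say that the numbers pair the samples. The 12 lists became 0 with an estimated correlation and 0 with fry. Of the 12 lists, the mean of oxidative phosphorylation turned direction (under the replicate block as given, and from −0.18 without db/db replicate 2 to 0.015 without db/db replicate 1). Means of lists not past the threshold also turned. With 1 array left out they ranged from −0.64 to 0.35 for cardiac muscle, −0.48 to 0.11 for skeletal muscle, −0.25 to 0.14 for immediate early genes, −0.26 to 0.016 for fatty acid uptake, −0.19 to 0.039 for cholesterol, −0.12 to 0.0059 for vasoactive, −0.098 to 0.075 for circadian, −0.075 to 0.20 for heat shock, −0.044 to 0.057 for fibroblast, −0.0089 to 0.035 for insulin, −0.0037 to 0.17 for interferon and −0.0076 to 0.017 for unfolded protein response genes. Under the replicate block cardiac muscle had 0.32 (adjusted p = 0.020), fibroblast −0.044, fatty acid uptake 0.016 and unfolded protein response −0.0021. Median centring gave −0.016 for fibroblast, −0.024 for insulin and −0.034 for unfolded protein response genes, which had −0.00016 with quantile normalization and −0.00026 with the filter at the 60th percentile. Brown adipocyte markers had −0.061 with that filter, cardiac muscle 0.027 with a pseudocount of 64, circadian genes 0.0066 with no filter, immediate early genes 0.011 with array weights and insulin genes −0.022 with the mean of a gene's probe sets. The endothelial, myeloid, glucocorticoid and fatty acid synthesis lists passed in 15 of the 15 settings that used camera with its preset correlation. Efnb2 ranged from −0.92 without db/db replicate 3 to 1.86 without db/db replicate 2, because its representative probe set switched to the second one without db/db replicate 1 or 3. Acta1 ranged from −2.06 without db/+ replicate 3 to 0.22 without db/+ replicate 2, Klf1 from −0.22 to 0.14 between the same settings, and Sc5d was 0.048 with the mean of a gene's probe sets. Where no construction is named, the cause was not tested. Over genes and settings, genes kept their direction and side of the threshold in 2180 cases, newly passed in 90 and no longer passed in 43. For lists these counts were 424, 23 and 43. They follow the adjusted p and not the size of a change. Lep, for example, no longer passed with a pseudocount of 1, where its log2 change was −3.65 against −2.96. Many of the genes passed in no setting, so the count of kept cases says little about stability. The direction turned in 5 cases for genes and 35 for lists. Signals near or under 39.5, such as Lep in db/db, may lie close to background, which was not measured here. Their changes depend on the pseudocount, as the range of Lep from −3.65 to −1.99 shows.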

Other observations

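Tests in this part were chosen after the results were seen, other than the counts of calls over splits of the arrays. A list of 7 measured mast cell markers was written after 2 of them, Tpsb2 and Mcpt4, had been seen to be lower in db/db. The other 5 had a mean log2 change of −0.38 (SE 0.05 over arrays) and a median of −0.25, with 4 of 5 negative. The mean of all 7 was −0.66. Camera on the 5 gave p = 0.00068 unadjusted, and p = 0.041 with an estimated correlation. The tryptase Tpsb2 had 43.5 ± 12.9 in db/db (n = 3) and 126 ± 4.88 in db/+ (n = 2), the chymase Mcpt4 had 46.0 ± 22.4 and 148 ± 32.2, the carboxypeptidase Cpa3 had 83 ± 3.68 and 148 ± 16.0 and the chymase Cma1 had 144 ± 20.7 and 262 ± 19.3. Over all probe sets 0 of the 7 passed with limma, and 4 were lower adjusted over the list alone. Mesothelial markers had a mean of −0.30 (SE 0.13), but without Prg4 and Slpi, which had been seen before the list was written, the mean of the other 9 was −0.07 (SE 0.16, camera p = 0.34 unadjusted; p = 0.67 with an estimated correlation), with Gpm6a at −0.51.

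Class II genes and complement genes were fixed beforehand as 1 list, which did not pass, and were looked at apart only after its members had been seen to go both ways. All 5 measured class II genes had a positive log2 change (mean 0.50, SE 0.21 over arrays), among them Cd74 with 882 ± 164 against 534 ± 73.5 and H2-Aa with 622 ± 62.1 against 422 ± 32.0, and 10 of 12 complement genes had a negative one (mean −0.30). Cd74 and H2-Aa were not past the threshold over all probe sets (limma adjusted p = 0.35 and 0.40).

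Lep, Sncg and Nnat, transcripts found in white fat, were far lower in db/db. Glucocorticoid responsive genes were lower too with camera's preset correlation. That list did not pass with an estimated correlation (camera adjusted p = 0.13) or with fry (adjusted p = 0.095). Both directions are unlike what is known, as leptin expression in fat and blood corticosterone are high in db/db mice. Less fat left on the db/db aortas would lower the other adipocyte markers too. Their median log2 change was −0.13 (SE 0.17 over arrays), above the bound of −0.91 set midway to the change of Sncg (−1.82). This argues against less fat as the whole cause of the lower Lep, Sncg and Nnat. Some loss of fat stays open, as 14 of 21 adipocyte markers other than Lep were lower. A smaller share of white against brown fat would lower Retn, another hormone of white fat, along with Lep. Retn had a log2 change of 0.49 (SE 0.20), the opposite direction. It did not pass the threshold (limma adjusted p = 0.60), so it does not decide and a smaller white share stays open. An exchange of the labels of both groups, which would turn every direction described here, cannot be told apart either, because the mutated gene Lepr had a log2 change of 0.26 (SE 0.17) and its probe set is not known to read the mutation. A genotype effect on these genes in the fat or wall stays open and was not tested.

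Alb, Bhmt and Serpina1b were lower in db/db, and liver fragments carried into both db/+ pools are a candidate explanation beside a genotype effect in the aorta or its fat, which was not tested. Of 18 hepatocyte markers not among the first 5 seen, 13 were lower. Their median log2 change of −0.64 lay below that of every one of 10000 random lists matched on signal. With the observed list counted in, the share is 0.010%, the smallest these draws can give. Such lists take genes as independent. Camera on these 18 markers gave p = 1.1e-05 with the preset correlation but p = 0.077 with an estimated one. Tat is among these 18 and is also a named member of the glucocorticoid list, so it may have been seen before the hepatocyte list was written. The markers therefore leave liver open without settling it. Apoa2 and Ttr, abundant in liver, had 97.4 ± 40.01 and 90 ± 45.4 in db/db (n = 3) against 283 ± 32.7 and 265 ± 23.97 in db/+ (n = 2). Against liver as the whole cause, Apoa1 had a log2 change of 0.81 (SE 0.24, limma adjusted p = 0.39) with a db/+ signal of 34.2, under the filter's level, so it does not decide, and Cyp2e1, which fat also expresses, had 0.86.

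The myeloid list was lower in db/db with camera's preset correlation. It did not pass with an estimated correlation (camera adjusted p = 0.35) or with fry (adjusted p = 0.11), and 0 of its 26 members passed over all probe sets. The lower markers were set against the makeup of the pools. Less adventitia would lower fibroblast markers alike, but the myeloid shift lay −0.50 (SE 0.10) from the fibroblast shift. A smaller share of all leukocytes would lower class II genes and lymphocyte markers with them. The myeloid shift lay −0.93 (SE 0.15) from that of the 4 class II genes outside the myeloid list, and between −1.01 and −0.82 with 1 array left out. Those genes were set apart only after they had been seen to be higher, so this distance cannot decide. The distance from the 8 lymphocyte markers, a list fixed beforehand, was −0.89 (SE 0.28). However, 3 of them had a mean signal under the filter's level in a group, so a smaller share of all leukocytes stays open. The array that stood apart, db/db replicate 1, did not carry it, since the shift without it was −0.51 against −0.48 (SE 0.09) with all arrays. Endothelial markers (−0.31) and the mast cell (−0.38) and hepatocyte markers (−0.36) not first seen had negative means too, so another tissue that holds several of these cell types, liver among them, stays open beside a genotype effect, and neither was tested for the myeloid markers.

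Of the 10 splits of the 5 arrays into 3 and 2, only 1, the true one, gave as many as 11 probe sets, and the highest other number was 0. At an unadjusted p under 0.05 the true split gave 1104 and the highest other 1115. For the 12 lists, 4 splits gave as many, and the highest other number was 16. With 10 splits no share under 0.05 can be had.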
